A study of Drosophila melanogaster with 4 samples.

How the data were processed

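Chromatin from the sieved heads of adult *Drosophila melanogaster* of the wild-type strain Oregon-R was studied by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody lot against histone H3 acetylated at lysine 18 (H3K18ac). Per the labels' protocols, tissue was homogenized and crosslinked with formaldehyde, and nuclei were lysed and sonicated before immunoprecipitation. The 4 samples are 2 ChIP libraries, replicates 1 and 2, and 2 input libraries of chromatin that was not immunoprecipitated. Each input is tied by its label to the region list of the ChIP replicate with the same number. The inputs therefore enter the values only through the authors' calls. Nothing in the labels says whether the 2 ChIP libraries came from separate collections of flies, so the spread between them may be technical.

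The data are 3 deposited lists of genomic regions, which the file headers place on FlyBase release 5 (r5) of the genome. There is 1 list per ChIP replicate and 1 list for the replicate set, which was made from the replicates together. Whether reads were pooled or calls were merged for the set is not given in the sources used here. Of the set's 8107 clusters, 2376 overlapped no cluster of either replicate list, which argues against a merge of those 2 lists alone. Bowtie 0.12.7 is named per the submitters' processing notes, without its role. The region caller, its thresholds and the number of reads are not given in the sources used here. Each region is marked per the file headers as enriched (called a cluster below) or depleted. Each region also carries a score deposited by the authors, which is negative in every depleted region and positive in every cluster of the 3 lists. The scale and log base of this score are not stated, so it served mainly to describe, rank and filter clusters within a list. Where scores of different lists are set side by side, a common scale is assumed and was not checked. No read counts were used, so the depth behind each value is unknown and no counting interval was computed. A deeper library generally allows weaker and narrower regions to be called, so differences in the number of clusters between lists can come from depth.

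The lists were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures were drawn with matplotlib 3.10.9. Clusters were counted, and the share of each sequence they cover was computed from the sequence lengths in the file headers, over 14 sequences of 168.7 Mb together. The 5 large arms are X, 2L, 2R, 3L and 3R, and the autosomal arms are the last 4 of these. The 6 sequences with Het in their names hold heterochromatin assembled apart from the arms, and U and Uextra hold unplaced sequence. Clusters of 10 kb or more are called broad. Clusters of 2 lists were counted as shared when they overlapped by at least 1 bp, and the Jaccard index is the bases in both lists as a percentage of the bases in either.

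Overlap of the replicate lists was compared with 1000 circular shifts of 1 list within each sequence. The one-sided permutation p of this test cannot be smaller than 0.001. It asks whether positions coincide beyond random placement, and it treats 2 libraries, not 2 conditions. The overlap procedure was tested on the 6380 clusters of replicate 1 against simulated lists made from them. In these lists a planted share was kept in place and the rest was circularly shifted. Shifted regions that overlapped a kept one were dropped, which lowered chance overlap. With 48.7% of regions planted as shared, it found 50.1% by reciprocal overlap, and with 79.7% planted it found 79.9%. With 0% planted it found 8.26%, and the permutation p of that single pair was 0.0099, as low as with planted regions. In 40 further pairs the replicate 1 list was set against a circular shift of itself. Of these, 3 had a p under 0.05 by any overlap and 2 by reciprocal overlap. The test uses the same shifts, so a share near 0.05 was fixed in advance. These pairs therefore do not show how the test behaves for 2 different lists that share only regional density. The planted regions were exact copies, so their recovery checked the counting only. It does not carry over to overlap of at least 1 bp, the main rule. By that rule 39.1% of replicate 1 clusters overlapped replicate 2 on average after shifts. No test between samples was run, because both ChIP libraries belong to 1 group. Means are given with the standard deviation (SD) of the 2 replicates. The median scores of X and autosomal clusters were compared within each list, with a 95% interval from 1000 bootstrap draws of 1-Mb blocks. That interval covers variation along the genome within a list and not between flies.

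Regions are named by a rule set before the data were examined. It takes the 10 widest clusters and the 10 clusters of highest score in the replicate set, and the 5 widest clusters seen in each replicate only. Regions are given by their coordinates in r5. The gene table used here belongs to release 6, and coordinates were not converted between releases, so no gene, exon or promoter was assigned to any region. For the same reason the planned tests at transcription start sites and of 19 gene lists were not run. Alternatives set in advance were a stricter overlap, the 50% of clusters with the highest score, joining clusters under 500 bp apart, the main arms alone, clusters per Mb, and each replicate list alone.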

Results

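H3K18ac is laid down in flies by the acetyltransferase CBP, encoded by *nejire*, and is generally found at active promoters and enhancers. It was mapped in adult heads, a tissue made up largely of brain, compound eye, fat body and muscle. The data comprise 2 ChIP replicates, each called by the authors against its own input, and a replicate set made from both. Replicate 1 had 6380 enriched clusters, replicate 2 had 6248 and the replicate set had 8107. The number of reads behind each list is unknown. All coordinates are FlyBase r5.

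The first question was how much of the fly genome carries the mark in heads and in what form. Clusters covered 32.3 Mb in replicate 1 and 29.8 Mb in replicate 2, or 25.9% ± 1.52 (SD, n = 2) of the 5 large chromosome arms. In the replicate set they covered 42.1 Mb, or 35.1% of these arms. Most clusters were short, with a median width of 2681 bp in replicate 1, 2588.5 bp in replicate 2 and 2399 bp in the set. A small part of them extended much further. Broad clusters of 10 kb or more made up 11.1% ± 1.09 (SD, n = 2) of the clusters in a replicate but 42.6% ± 2.96 (SD, n = 2) of the covered bases. The set held 1034 broad clusters, with 51.1% of its covered bases. Wider clusters had higher scores, the authors' value for each region. Across clusters, which are not independent replicates, the Spearman correlation of width and score was 0.784 in replicate 1, 0.754 in replicate 2 and 0.693 in the set.

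The widest cluster of H3K18ac as called lay on 3R from 5694794 to 5809902 and spanned 115 kb, with a score of 1.41 in the replicate set. Each replicate called it as 1 cluster, which covered 99.9% of the domain in replicate 1 and 99.5% in replicate 2. A domain of 112 kb lay on 3R from 13720560 to 13832832, and one of 108 kb on 3L from 10300910 to 10408904. Of the 10 widest clusters of the set, 5 were on 3L, 3 on 3R, 1 on 2L, 1 on 2R and 0 on the X. The other domains on 3L ran from 17086716 to 17180610 (93.9 kb), 19139920 to 19228662 (88.7 kb), 736976 to 825344 (88.4 kb) and 5188274 to 5275302 (87.0 kb). The remaining domains were on 2R from 17282704 to 17368664 (86.0 kb), on 2L from 4229506 to 4314150 (84.6 kb) and on 3R from 21341310 to 21423562 (82.3 kb). All 10 were covered to at least 90.8% in replicate 1 and 88.3% in replicate 2. Except for the widest, they were divided into several clusters in both replicates. The 93.9-kb domain on 3L, for example, consisted of 11 clusters in replicate 1 and 8 in replicate 2. When clusters under 500 bp apart were joined, the widest domain of the set was instead on 3L from 17086716 to 17231576 (145 kb), ahead of 3R from 5675626 to 5809902 (134 kb), which stayed the widest in both replicates. The scores of the 10 clusters in the set ranged from 0.747 to 1.41.

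**Figure D1:**
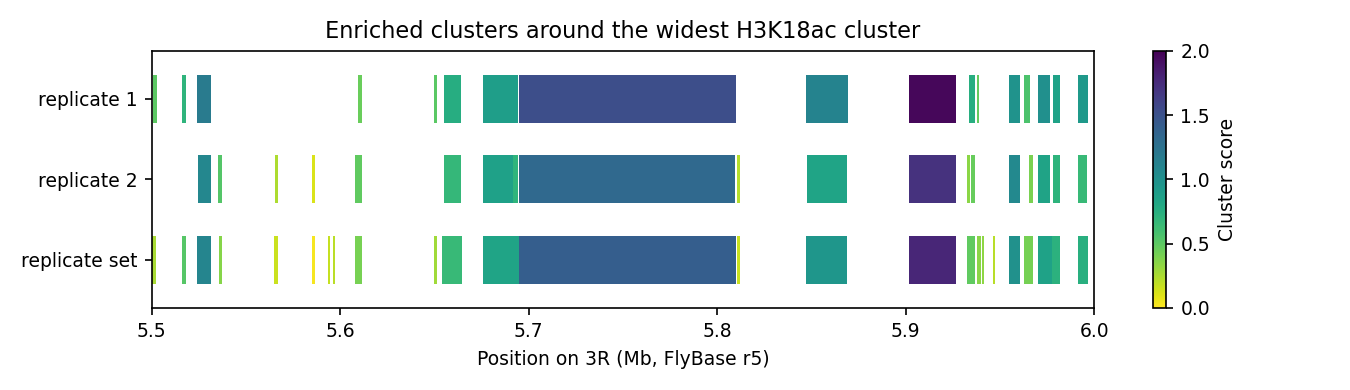
Enriched clusters on 3R between 5.5 and 6 Mb in each list, drawn to scale along the horizontal axis (Mb, FlyBase r5) and coloured by the authors' score. The 115-kb domain is a single block in all 3 rows, and the 24.8-kb cluster to its right has the higher score, 1.78 in the replicate set.

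Among the 10 clusters of highest score in the replicate set, 6 were present in both replicates and ranged from 17.3 kb to 29.3 kb. The highest of these was on 2L from 6073852 to 6094214, with a score of 1.86 in the set, 1.99 in replicate 1 and 1.81 in replicate 2. In each replicate this was the highest score of the whole list. It was followed by clusters on 3R from 5901910 to 5926708 (1.78 in the set), on 2R from 5428820 to 5455130 (1.74), on 3R from 5242876 to 5272208 (1.68), on the X from 2175162 to 2203790 (1.67) and on 3R from 3930608 to 3947892 (1.61). The other 4 overlapped no cluster of either replicate and were 1001 to 1039 bp wide. They lay on 2R from 3155758 to 3156796 (2.62), on U from 1176332 to 1177332 (2.14), on 2L from 7983032 to 7984046 (1.99) and on 2R from 13124014 to 13125014 (1.92). All 4 are narrower than 1301 bp, the width of the narrowest cluster in each replicate list.

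The 2 replicates were next compared for the position and strength of their clusters. Of the replicate 1 clusters, 78.7% overlapped a cluster of replicate 2, against a mean of 39.1% and a maximum of 42.0% after 1000 circular shifts (one-sided permutation p = 0.001, the smallest possible). Of the replicate 2 clusters, 84.6% overlapped one of replicate 1, against a mean of 40.5% and a maximum of 43.3% after shifts (permutation p = 0.001). The replicates shared 26.2 Mb, and the Jaccard index of covered bases was 72.7% against 14.8% on average after shifts (permutation p = 0.001). Clusters that matched 1 to 1 also ranked alike. Among 3247 clusters that overlapped exactly 1 cluster of the other list, which in turn overlapped no other, the Spearman correlation between replicates was 0.786 for score and 0.808 for width. The Pearson correlations were 0.856 for score and 0.905 for log width. These correlations are across clusters and not across independent samples. They leave out clusters seen in 1 list only and those divided in the other list. Replicate 1 had the higher score in 69.6% of the pairs and the wider cluster in 60.9%.

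Replicate 1 had 1361 clusters with no counterpart in replicate 2, and replicate 2 had 963 with none in replicate 1. They were short and of low score. Their median width was 1651 bp in replicate 1, against 3386 bp for shared clusters, and 1615 bp in replicate 2, against 3065 bp. Their median score was 0.525 against 0.663 in replicate 1 and 0.503 against 0.611 in replicate 2. They made up 7.79% of the covered bases of replicate 1 and 5.68% of those of replicate 2. None of the 758 broad clusters of replicate 1 and none of the 646 of replicate 2 was among them. A wider cluster meets the rule of 1 bp more easily, and width rises with score. Part of these contrasts in width and score can therefore come from the rule itself. The widest seen in replicate 1 only was 9282 bp on 3R from 25382013 to 25391294, followed by 2L from 7568539 to 7575877, 3L from 80998 to 88139, X from 8361082 to 8366694 and 3R from 14618971 to 14624496. The widest seen in replicate 2 only was 5574 bp on 2R from 19067948 to 19073521, followed by X from 15861958 to 15867303, 3LHet from 223527 to 228431, 2L from 17816054 to 17820830 and 3R from 7780905 to 7785669. Each of these 10 regions was covered to at least 84.8% by clusters of the replicate set. Among the 50% of clusters with the highest score, 217 of replicate 1 and 218 of replicate 2 had no counterpart in the whole other list.

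The replicate set was compared with the lists of the single replicates. It recovered 99.3% of the replicate 1 clusters and 99.5% of the replicate 2 clusters. Of its own 8107 clusters, 3888 overlapped clusters of both replicates, and these held 82.0% of its covered bases with a median width of 5442 bp. A further 1096 overlapped replicate 1 only and 747 overlapped replicate 2 only. The remaining 2376, or 29.3%, overlapped neither, had a median width of 1275 bp and held 8.13% of the covered bases. Of these, 1122 were at least as wide as the narrowest cluster of the replicate lists. The set was not drawn on the same positions as the replicate lists: 100% of its starts and ends were even numbers, against 51.1% of the starts in replicate 1 and 49.8% in replicate 2, and its narrowest cluster was 1001 bp, against 1301 bp. Widths in the set and in the replicates, and the number seen in neither, therefore include any difference in how the lists were called.

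The mark was compared between chromosomes, among them the X, which males carry in a single, dosage-compensated copy, and chromosome 4, a small and largely heterochromatic chromosome. The flies were a mixed adult population, and the sexes were not analysed apart. Coverage of the large arms lay close together, with means (± SD, n = 2) of 24.6% ± 0.195 on the X, 24.5% ± 1.70 on 2L, 27.4% ± 1.99 on 2R, 25.9% ± 1.84 on 3L and 27.0% ± 1.79 on 3R. Within each of the 3 lists the X was covered less than the autosomal arms together (26.2% ± 1.82), although the means differed by less than the autosomal SD. Their ratio was 0.900 in replicate 1, 0.982 in replicate 2 and 0.986 in the set. Chromosome 4 was covered to 8.20% in replicate 1 and 12.7% in replicate 2, below every large arm in both. Its coverage in the set was 0.433 times that of the autosomal arms, whereas its clusters per Mb were 0.764 times theirs. The assembled heterochromatic sequences had 28 clusters in replicate 1 and 36 in replicate 2, and 0.800% ± 0.246 (SD, n = 2) of their length was covered. No cluster lay on the Y heterochromatin sequence in any of the 3 lists. Mappability was not measured, and repeated sequence can lack reads for that reason alone.

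**Figure D2:**
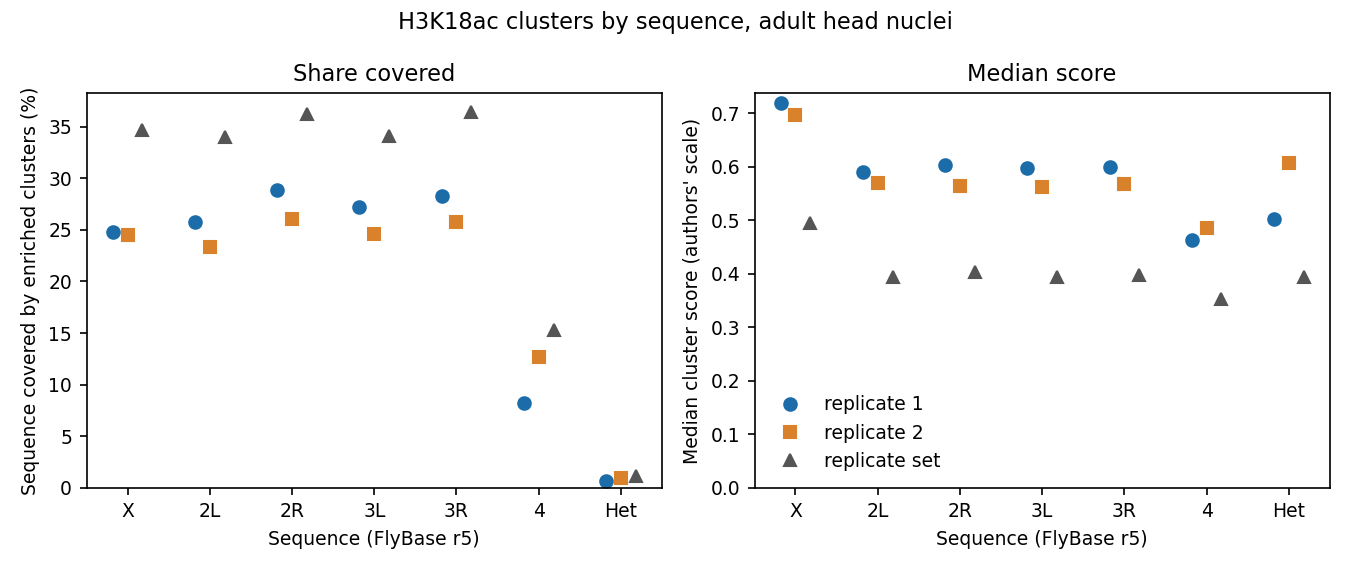
Share of each sequence covered by enriched clusters (left, percent) and median cluster score on the authors' scale (right) for the 5 large arms, chromosome 4 and the heterochromatic sequences together (Het). Circles are replicate 1, squares replicate 2 and triangles the replicate set. Chromosome 4 and Het lie below the large arms in coverage, and the X lies above the other sequences in score.

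Although the X was covered about as much as the autosomal arms, its clusters had higher scores. The median score on the X was 0.719 in replicate 1 and 0.698 in replicate 2, against 0.597 and 0.566 on the autosomal arms. The difference was 0.122 in replicate 1 (95% block bootstrap interval 0.104 to 0.136) and 0.132 in replicate 2 (0.117 to 0.145). In the replicate set it was 0.0974 (0.0884 to 0.104). If the 2 replicate lists share a score scale, it exceeded the spread between them, whose SD was 0.0149 for the X median and 0.0219 for the autosomal median (n = 2). The medians of the autosomal arms lay between 0.590 and 0.603 in replicate 1 and between 0.562 and 0.569 in replicate 2. Chromosome 4 had a lower median score than any large arm, 0.463 in replicate 1 and 0.486 in replicate 2. How the score was scaled between ChIP and input is not given in the sources used here.

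**Figure D3:**
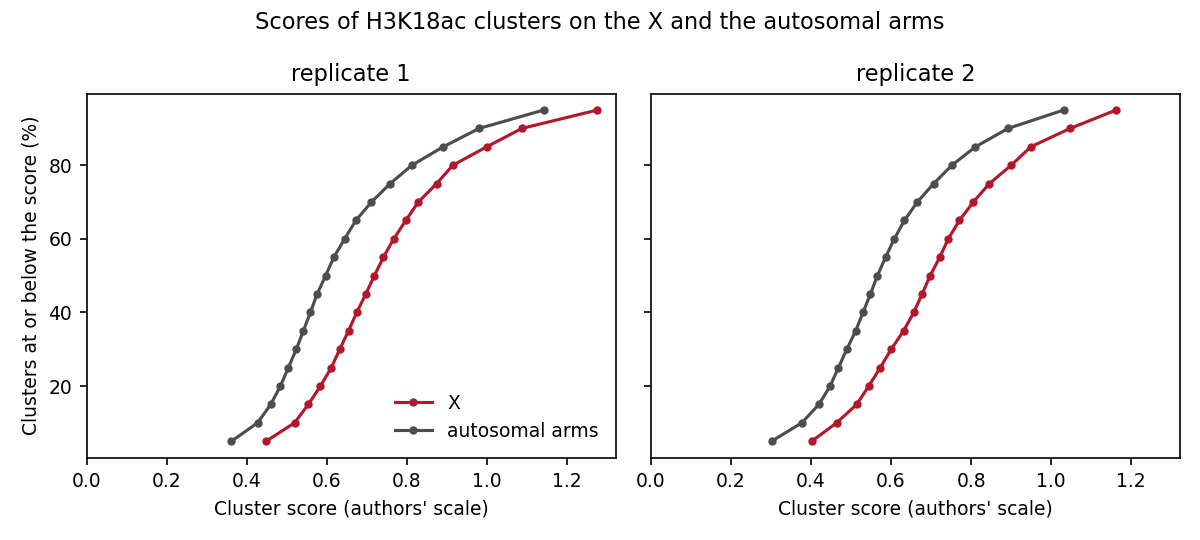
Cumulative share of clusters (vertical axis, percent, in steps of 5) at or below each score (horizontal axis, the authors' scale) on the X and on the 4 autosomal arms together, in replicates 1 and 2. The X curve lies to the right of the autosomal curve at each point drawn in both replicates, with medians of 0.719 against 0.597 and 0.698 against 0.566.

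Along the X, 2L, 2R and 3L, average coverage was lower in the part next to the centromere. In the centromere-proximal 10% of the X, 9.78% ± 0.378 (SD, n = 2) of the sequence was covered, against 26.3% ± 0.175 in the rest of the arm. The same comparison gave 12.8% ± 0.651 against 25.8% ± 1.82 on 2L, 11.4% ± 0.955 against 29.2% ± 2.31 on 2R and 13.7% ± 0.584 against 27.2% ± 1.98 on 3L. These 4 differences are larger than the spread between replicates. On 3R the gradient was shallow, and coverage of the proximal part was 0.916 ± 0.00656 (SD, n = 2) times that of the rest of the arm. Among 236 windows of 500 kb, the least covered was at the proximal end of 3L, from 24000001 to 24500000, with 0.384% ± 0.0680 (SD, n = 2). The windows covered most in the set were on 3L from 10000001 to 10500000 (68.3%), which holds the 108-kb domain, and from 22000001 to 22500000 (66.2%). The latter lies mostly within the centromere-proximal 10% of 3L, which begins at 22089203, so coverage within that part was uneven. Window coverage in the replicates was correlated (Pearson 0.978, Spearman 0.976, across windows). It was higher in replicate 1 in 189 windows and in replicate 2 in 47.

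**Figure D4:**
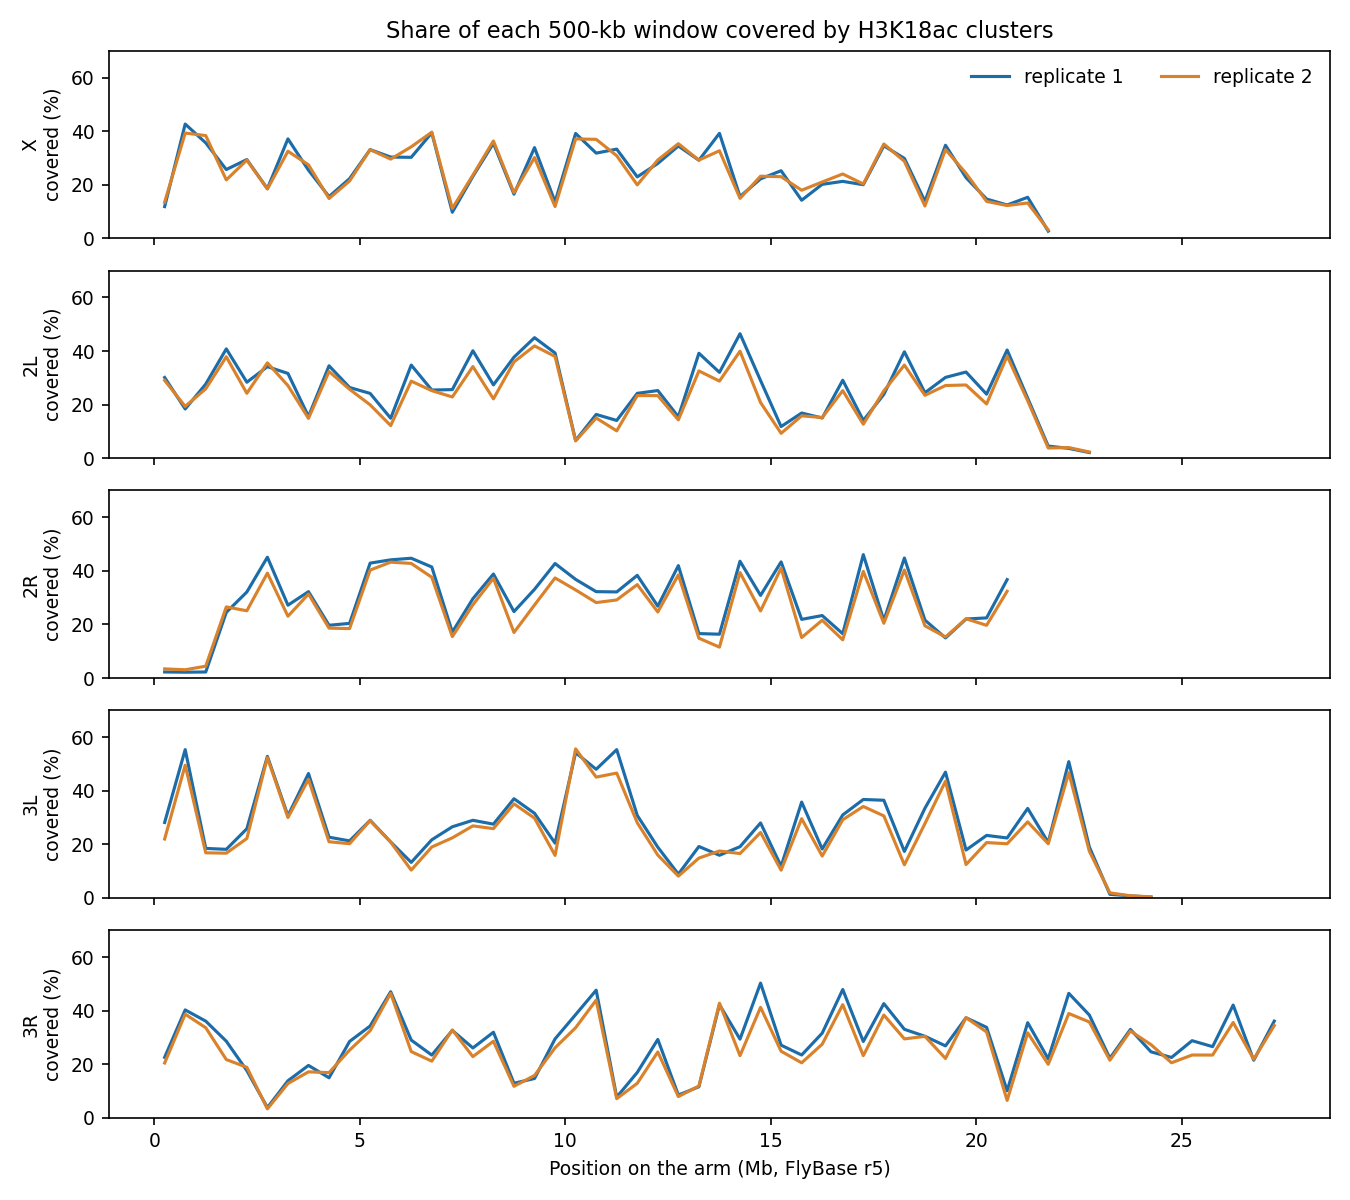
Share of each 500-kb window covered by enriched clusters (vertical axis, percent) along the 5 large arms (horizontal axis, Mb, FlyBase r5) in replicate 1 and replicate 2. The lines of the replicates run close together, and coverage falls toward the proximal ends of X, 2L, 2R and 3L.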

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

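The comparison with single-replicate calls given here was chosen after the depleted regions had been seen.

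Regions marked as depleted in the deposited lists entered no comparison of the report. The replicate set held 18 of them, 29.3 kb in all, and each replicate list held 1. The 18 drew attention as a signal in records outside the enriched clusters on which the report rests. They were 1349 to 1773 bp wide, with 7 on 3R and 0 on the X. Their scores ran from -0.0949 to -0.00027. Of the 18, 11 coincided with an enriched cluster in at least 1 replicate, 2 of them in both. Those enriched clusters had scores between 0.00274 and 0.190, below the median of 0.619 in replicate 1 and 0.588 in replicate 2. The depleted region of replicate 1, on 3L from 3901530 to 3903057, was enriched in replicate 2 with a score of 0.409 and in the set with 0.194. The depleted region of replicate 2, on 2L from 10262426 to 10263903, was enriched in replicate 1 with a score of 0.135 and in the set with 0.0502. The cause was not tested, and no biological explanation was tested.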

How the results depend on the processing

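The alternatives for the number of clusters, for the widest cluster, for clusters with a score under 0.1, for a minimum width, for the X score and for chromosome 4 were chosen after the data had been seen, as was that of rank agreement on the main arms. Of 42 alternative values, 32 kept their side of the test or stayed within the limit set for them and 10 moved, among them the X to autosome ratio, which crossed 1. The limits differed between results, so a value counted as kept can have changed by more than one counted as moved. The overlap of the replicates stayed above all 1000 shifts under each alternative tried. The share of shared clusters ranged from 58.6% (replicate 1, reciprocal overlap of at least 50%) to 84.7% (replicate 2, main arms alone), and the Jaccard index from 71.4% to 73.1%. Joining clusters under 500 bp apart left 5372, 5353 and 6421 clusters in replicate 1, replicate 2 and the set, and widened the widest of the set from 115 to 145 kb, at another place. When the 50% of clusters with the highest score in 1 list were compared with the whole other list, 217 were seen in replicate 1 only (from 1361) and 218 in replicate 2 only (from 963), in part because fewer clusters were counted. Restricting the set to clusters at least as wide as the narrowest in the replicate lists left 1122 seen in neither (from 2376), by construction. The X to autosome ratio of 0.986 became 1.10 in clusters per Mb and 0.900 to 0.982 in single replicates. The chromosome 4 ratio of 0.433 became 0.764 in clusters per Mb and stayed below 1. It was 0.298 in replicate 1 and 0.509 in replicate 2, and both counted as kept. The X minus autosome score of 0.0974 became 0.0878 at matched width and 0.122 to 0.132 in single replicates, whose scores run higher than those of the set. For the other changes the cause was not tested. No paired analysis was possible because the inputs that share replicate numbers with the ChIP libraries enter only through the calls. The planned results at transcription start sites and for gene lists, with their alternatives, were not run. The depth of the libraries is unknown, so weak or narrow regions seen in 1 list only cannot be called absent from the other.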

Other observations

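The tests of X scores, of chromosome 4 and of clusters seen only in the replicate set were chosen after the results they weigh had been seen. The exceptions, set before their own outcome was known, are the comparison of chromosome 4 with stretches of its length and that of scores over all set clusters of at least 1301 bp seen in neither replicate, although the minimum of 20 clusters per width bin in the latter and the look at thinly covered stretches in the former were added afterwards.

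Chromosome 4 and the heterochromatic sequences differed between the replicates in the share of clusters seen in 1 list only. Of the chromosome 4 clusters, 3 of 41 (7.32%) in replicate 1 and 21 of 56 (37.5%) in replicate 2 had no counterpart. In the heterochromatic sequences these were 2 of 28 in replicate 1 and 11 of 36 in replicate 2. On the large arms the direction was the opposite, with 21.5% in replicate 1 and 15.1% in replicate 2. Broad clusters were somewhat less dense on the X, at 5.17 ± 0.252 per Mb (SD, n = 2) against 6.05 ± 0.783 on the autosomal arms, a difference close to the spread between replicates. Within lists, the ratio of X to autosomal arms was 0.810 in replicate 1, 0.909 in replicate 2 and 0.905 in the set.

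Wider X clusters are argued against as the cause of the higher X scores, since X clusters were narrower than autosomal ones in replicate 1 (median 2606 against 2726 bp) and replicate 2 (2597 against 2624 bp), and in the set, where they were wider, the difference at matched width was 0.0878 (95% interval 0.0825 to 0.0964). If a higher score needed for a call on the X affected weak clusters only, the difference would vanish in the top quartile of cluster width. It was 0.108 there in replicate 1 (0.0705 to 0.159). A higher limit could also shorten clusters, so this comparison by width cannot exclude fewer X reads as a cause. Chance position along the genome was not seen to give it: 0 of 75 overlapping autosomal stretches of the length of the X reached the difference in replicate 1, where the largest was 0.0219. Few separate stretches of 22.4 Mb fit in the 96.6 Mb of the autosomal arms, so the 75 are not independent and chance is not excluded. A constant offset from scaling ChIP to input stays open, since the narrowest and widest quartiles of replicate 1 had overlapping intervals, whereas in replicate 2 the widest quartile reached 0.172 (0.142 to 0.205) against 0.111 (0.0952 to 0.139) in the narrowest. No biological explanation was tested, as the sexes were not analysed apart.

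The share of chromosome 4 covered was 1.55 times as high in replicate 2 as in replicate 1. Looser calling throughout replicate 2 is argued against by the ratio of 0.921 on the 5 large arms. A chance difference in a stretch of this length stays open: 1 of 86 stretches of the large arms had a ratio as high, at the proximal end of 2R (1.57), but most stretches were well covered, and this was 1 of the 7 with under 15% covered in replicate 1. Of these 7, 3 had a ratio above 1, at the proximal ends of 2R, 3L (1.19) and 2L (1.05). The others were below 1, among them the most proximal stretch of the X (0.938). The stretch on 2R therefore cannot tell chance from a difference shared by centromere-proximal sequence. The heterochromatic sequences together had a ratio of 1.56, with 4 of the 5 that hold clusters above 1, consistent with a difference in how heterochromatic sequence was recovered or scaled against input, although this rests on 58.1 kb and 90.4 kb of covered sequence. No biological explanation was tested, as both libraries belong to 1 group.

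Of the 2376 set clusters seen in neither replicate, 52.8% were narrower than any replicate cluster, so a smaller minimum width in the set could account for those. For the 1122 others this stays open too. Called replicate clusters were narrower than in the set, by a median ratio of 0.917 (replicate 1) and 0.858 (replicate 2). Regions narrower than 1301 bp in a replicate are missing from these ratios. The ratios therefore cannot tell how many of the 1122 fell under that limit in a replicate. Weakness in a single replicate predicts lower scores than in set clusters seen in both, as the medians without matching were (0.348 against 0.572), but at matched width the scores of the 557 that could be compared were higher by 0.0513 (0.0412 to 0.0722). By width, the 342 compared clusters under 2000 bp were higher by 0.105 (0.0983 to 0.112) than 217 clusters seen in both. This argues only against a low set score as the reason they were not called. The 215 of 2000 bp or more differed by -0.0928 (-0.109 to -0.0739), as weakness predicts. Strength in a single replicate was not measured where no cluster was called, so weakness there is not excluded for either part. The other 565, all narrower than 1621 bp, had fewer than 20 clusters seen in both at their width and stay open, and no biological explanation was tested.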
